A study of Mus musculus with 15 samples.

How the data were processed

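Transcript levels were measured with Affymetrix Mouse Gene 1.0 arrays on RNA of isolated small intestinal epithelial cells from 15 samples, 3 in each of 5 groups. Per the labels, RNA was purified with a Qiagen RNeasy Mini kit and labelled with biotin by the whole transcript sense protocol. The deposited values, which the authors made in Partek, are on a log2 scale, 1 value for each of 35556 transcript clusters. The Partek version, the background correction, the normalization and the summarization were not given in the sources used here. That the values are log2 was read from their range and their near-equal quantiles between arrays. For arrays, their number limits the precision.

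Of the transcript clusters, 21789 carried exactly 1 gene symbol, 1621 carried several and 12146 were absent from the annotation used here. The last 2 kinds were tested apart and enter no gene count. The mouse reference gene table served for names only, so no coordinates are given. The 21789 clusters covered 19938 symbols. For the 999 symbols with several clusters, the cluster with the highest mean over all arrays was used. A gene was tested when its largest group mean exceeded the median of all values in the table, 4.91 on the log2 scale. This removed 8154 genes and left 11784, of which 810 had several clusters.

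A linear model with 1 mean per group was fitted to all 15 arrays in R 4.3.3 with limma 3.58.1, which left 10 residual degrees of freedom, and variances were moderated with eBayes. Tests were two-sided, with the Benjamini-Hochberg correction over the genes tested within a comparison and a threshold of 0.05, at which a gene is called. Comparisons were wild-type jejunum against ileum, cKI against control ileum, cKO against wild-type jejunum, control against wild-type ileum, cKI ileum against wild-type jejunum and cKO jejunum against wild-type ileum. Simulated data sets, 100 in number, gave the correlation and covariance that shared arrays alone produce between differences. In 100 more, added after the result was seen, each group was given the means of the wild type of its region, and the shift of the regional genes was measured.

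Regional genes were those called between wild-type jejunum and ileum at least 2-fold. The regional index of an array was the mean of its jejunum-high genes minus the mean of its ileum-high genes, scaled to 0 in the wild-type ileum and 1 in the wild-type jejunum. It was compared with exact two-sided permutation tests, where 3 against 3 arrays cannot go below 0.1.

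There were 30 fixed gene lists with 537 symbols, 502 of them distinct and 453 named by the table. They covered GATA and intestinal transcription factors, jejunal and ileal textbook markers, bile acid, cobalamin, sugar, lipid, cholesterol, fatty acid oxidation, iron and folate, calcium, retinoid, amino acid and drug genes. Others covered Paneth, goblet, enteroendocrine, tuft and stem cells, proliferation, antimicrobial, interferon, MHC class II and isolation stress genes. The rest held T and NK, B and plasma, myeloid, stromal, endothelial and glial cells, and pancreas with erythrocytes. The 28 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01 and again with an estimated one, with the Benjamini-Hochberg correction over lists.

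Genes are named by a fixed rule. It takes Gata4, Gata5 and Gata6 in every comparison, and the 10 largest rises and 10 largest falls among called genes (5 and 5 for control against wild-type ileum). It also takes up to 4 members of each list by smallest p, and 10 genes per direction called in the regional, cKI and cKO comparisons with the knockin toward jejunum and the knockout toward ileum. A gene named in one comparison may be given in others.

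The labels do not say whether equal replicate numbers mark the same animals. After removal of group means, arrays of equal number correlated by 0.334, 0.216 and 0.161 across genes for wild-type jejunum and ileum, and by 0.128, 0.177 and 0.258 for cKI and control, above a preset limit of 0.1. They did so by 0.185, -0.0247 and -0.0732 for cKO and wild-type jejunum, and by -0.103, -0.265 and -0.00722 for control and wild-type ileum. By that limit, which is no test of pairing, the numbers paired the arrays in the first 2 comparisons and not in the last 2. The model, fixed beforehand, had no replicate term, and the number was tried as a block. The exact permutation tests took no account of pairs.

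The steps were tested on simulated data with 200 genes changed per comparison, 50 at each of 1.5-fold, 2-fold, 4-fold and 8-fold. Of these, 60%, 98%, 100% and 100% were recovered in the layout of jejunum against ileum, and 50%, 78%, 100% and 96% in that of cKI against control. It was 54%, 88%, 100% and 100% for cKO against wild-type jejunum and 56%, 88%, 98% and 98% for control against wild-type ileum. Each recovered gene had the right direction. Of the calls 4.59%, 6.82%, 3.3% and 4.86% were false. A list shifted 1.5-fold was called in each of the 4 layouts, and 1 unshifted list was called in the cKI layout. The simulated noise was independent between genes, so this does not test list calls where genes are correlated.

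Alternatives were no level filter, a filter at the 75th percentile, quantile normalization, centring, only the 6 arrays compared, eBayes with trend and robust, no moderation, array weights, the mean over clusters of a gene, a replicate block over all arrays, each array left out, and a minimum of 2-fold. For the cKO comparison the difference between control and wild-type ileum was also subtracted. A replicate block within each set of mice and a covariate of stromal markers were added after the data were seen.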

Results

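Transcript levels were measured in epithelial cells isolated from the mouse small intestine, on 15 Affymetrix Mouse Gene 1.0 arrays in 5 groups of n = 3 arrays. The groups were the ileum and the jejunum of wild-type CD1 mice, the ileum of mice with a conditional Gata4 knockin (cKI), the ileum of their controls, and jejunum from mice with a conditional Gata4 knockout (cKO). Gata4 encodes a transcription factor of the proximal small intestine. The labels pose the question of whether Gata4 sets jejunal against ileal gene expression, and name no jejunal control for the cKO. Deposited log2 values had array medians from 4.82 to 5.0, and the number of arrays limits the precision. Of 19938 genes with a symbol, 11784 were tested. Log2 differences are given as first group minus second, ± the standard error from limma. Adjusted p-values are from limma with the Benjamini-Hochberg correction over all genes tested, and group means carry the SD of n = 3 arrays. The labels do not say that arrays of 1 group came from separate animals, so p-values measure only the spread between these samples. Gene lists were written before the data were examined, as were the comparisons, the threshold, the named-gene rule and all alternatives except 2.

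The wild-type jejunum and ileum differed in genes of bile acid recovery and nutrient digestion, among others. Fabp6, which carries bile acids inside the enterocyte, differed by -8.28 ± 0.24 between jejunum and ileum (adjusted p = 2.63e-11). Slc10a2, the apical sodium bile acid transporter, differed by -6.82 ± 0.291 (adjusted p = 9.69e-10). Fabp1, a fatty acid carrier of the proximal enterocyte, was higher in the jejunum by 8.19 ± 0.645 (adjusted p = 4.76e-07). Lct, which encodes lactase, was higher by 7.13 ± 0.596 (adjusted p = 7.73e-07). The comparison asks which genes mark each region when Gata4 is unmodified.

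Gata4 itself (transcript cluster 10420747) was at 9.53 ± 0.13 in the jejunum and 5.6 ± 0.34 in the ileum, a difference of 3.93 ± 0.185 (15.2-fold, adjusted p = 2.38e-09), and was higher in 3 of 3 jejunal arrays. Gata6, its paralog, was higher by 0.79 ± 0.0997 (adjusted p = 4.09e-05). Gata5 differed by 0.16 ± 0.181 (adjusted p = 0.603). Zfpm1, a cofactor of GATA proteins, and Onecut2, a homeobox factor, were higher in the jejunum by 1.65 ± 0.142 and 3.18 ± 0.168. Foxa1, a forkhead factor, differed by -1.36 ± 0.122. In the list of GATA and intestinal transcription factors, 6 genes were higher, 4 lower and 10 not passed, and 7 and 4 adjusted over the list alone. Its median was -0.03, its mean was 0.48, and its camera direction was up (adjusted p = 0.377).

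Many genes of sugar and fat handling were higher in the jejunum. Slc2a2, the basolateral glucose transporter, was higher by 6.63 ± 0.481, and Slc2a7, a fructose and glucose carrier, by 3.51 ± 0.295. In the list of sugar digestion and transport, 14 of 15 genes were higher (14 adjusted over the list alone, camera adjusted p = 1.48e-15, and adjusted p = 0.07491 with an estimated correlation). Cd36, a fatty acid translocase, was higher by 5.5 ± 0.365, and Dgat2, which makes triglycerides, by 2 ± 0.195. Of the lipid absorption list, 22 of 24 genes were higher (22 adjusted over the list alone; 2.86e-14, and adjusted p = 0.1465 with an estimated correlation). Pdk4, a PPAR target that spares glucose, was higher by 3.53 ± 0.254, and Ehhadh, a peroxisomal oxidation enzyme, by 1.43 ± 0.13. In fatty acid oxidation, 15 of 17 genes were higher (15 adjusted over the list alone; 6.92e-11, and adjusted p = 0.06079 with an estimated correlation).

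Lists of retinoid, iron and folate, and drug metabolism genes were also called higher in the jejunum at the preset correlation. Rdh7, a retinol dehydrogenase, was higher by 4.26 ± 0.352, and Slc46a1, the folate transporter, by 3.76 ± 0.228. In retinoid metabolism 8 genes were higher, 1 lower and 3 not passed (8 and 1 adjusted over the list alone, camera adjusted p = 3.33e-05, and adjusted p = 0.06079 with an estimated correlation). In iron and folate absorption 5 were higher, 1 lower and 5 not passed (5 and 1 adjusted over the list alone; 0.00741, and adjusted p = 0.2883 with an estimated correlation). Cyp2b10, a xenobiotic-induced cytochrome, was higher by 7.23 ± 0.33, and Adh1, an alcohol dehydrogenase, by 4.63 ± 0.375. In drug metabolism 19 genes were higher, 3 lower and 5 not passed (22 and 3 adjusted over the list alone; 8.2e-12, and adjusted p = 0.07508 with an estimated correlation). In amino acid and peptide uptake 9 were higher, among them Slc36a1, a proton-coupled carrier (3.1 ± 0.259), and 3 lower, among them Naaladl1, a brush border peptidase (-2.36 ± 0.208), with 7 not passed (10 and 3 adjusted over the list alone). Its camera adjusted p was 0.00928, and adjusted p = 0.5738 with an estimated correlation; without wild-type ileum replicate 2 it was 0.056. Of the jejunal markers from textbooks, 14 of 17 were higher and 2 lower (14 and 2 adjusted over the list alone; 1.37e-10, and adjusted p = 0.0926 with an estimated correlation).

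Lists called lower in the jejunum, and so higher in the ileum, were those of bile acid uptake, cholesterol synthesis and goblet cells, among others. Nr1h4, the bile acid receptor FXR, differed by -1.77 ± 0.159. In bile acid uptake 1 gene was higher in the jejunum, 6 lower and 4 not passed (1 and 7 adjusted over the list alone, camera adjusted p = 2.27e-06, and adjusted p = 0.05403 with an estimated correlation). Ileal textbook markers had 10 of 18 lower and none of the 18 higher (0 and 11 adjusted over the list alone; 1.86e-07, and adjusted p = 0.125 with an estimated correlation). Sqle, which makes squalene epoxide, and Cyp51, a sterol demethylase, differed by -2.41 ± 0.166 and -1.78 ± 0.159. In cholesterol synthesis 16 of 20 genes were lower (17 adjusted over the list alone; 5.15e-16, and adjusted p = 0.06079 with an estimated correlation). Agr2, a disulfide isomerase of mucus cells, and Atoh1, which specifies the secretory lineage, differed by -1.15 ± 0.0958 and -1.08 ± 0.0981. Goblet cell genes were lower in 14 of 16 cases (14 adjusted over the list alone; 2.86e-14), and this list alone of the 28 tested held with an estimated correlation (adjusted p = 0.02034).

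Crypt and defence genes also differed. Lgr5, a Wnt-dependent stem cell receptor, differed by -0.79 ± 0.17 (adjusted p = 0.00342). In the stem cell list 6 of 17 genes were lower (8 adjusted over the list alone, camera adjusted p = 0.0236, and adjusted p = 0.3369 with an estimated correlation). It was 0.0792 without wild-type ileum replicate 2 and 0.0655 without wild-type jejunum replicate 1. Of Paneth cell genes 3 of 10 were lower, among them Nupr1, a stress regulator (-1.43 ± 0.188; 4 adjusted over the list alone; list 0.00741, and adjusted p = 0.2962 with an estimated correlation). Duox2, an epithelial NADPH oxidase, and Nos2, which makes nitric oxide, differed by -4.06 ± 0.392 and -3.75 ± 0.36, whereas Reg1, a lectin of the proximal gut, was higher by 7.1 ± 0.361. The antimicrobial list had 1 higher, 5 lower and 8 not passed (1 and 5 adjusted over the list alone; 0.00405, and adjusted p = 0.1638 with an estimated correlation). Ifit1, induced by type I interferon, was higher by 2.81 ± 0.374, with 13 of 19 interferon genes higher (15 adjusted over the list alone; 1.39e-06, and adjusted p = 0.2657 with an estimated correlation). Enteroendocrine genes went both ways: Gip, of K cells, was higher by 2.83 ± 0.311, and Pyy, of distal L cells, differed by -1.66 ± 0.267 (3 higher, 3 lower, 13 not passed; 5 and 3 adjusted over the list alone; 0.408).

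Of lists for other cell types, those of stroma and of B and plasma cells were called lower in the jejunum at the preset correlation. Myh11, of smooth muscle, differed by -1.4 ± 0.297, and 8 of 14 stromal genes were lower (13 adjusted over the list alone, camera adjusted p = 8.92e-07, and adjusted p = 0.2378 with an estimated correlation). Of B and plasma cell genes 3 of 8 were lower (7 adjusted over the list alone; 0.00618, and adjusted p = 0.3213 with an estimated correlation). H2-Aa, an MHC class II chain, differed by -1.11 ± 0.204, with 3 of 6 class II genes lower (3 adjusted over the list alone; 0.00618, and adjusted p = 0.2992 with an estimated correlation). Lists not called were cobalamin uptake (1 higher, 1 lower of 7; 2 and 1 adjusted over the list alone; 0.73), calcium and vitamin D (3 and 3 of 8; 0.406), tuft cells (3 higher of 12; 0.194) and proliferation (0 of 23; 0.11). Proliferation was called lower without wild-type ileum replicate 1 (0.00983) or wild-type jejunum replicate 3 (0.041). Nor were isolation stress genes (2 higher of 16; 0 adjusted over the list alone; 0.699), T and NK cells (1 lower of 11; 0 adjusted over the list alone; 0.687) and myeloid cells (2 lower of 10; 0.167). For endothelium and glia 1 member was tested, Lyve1 (-0.12 ± 0.156, adjusted p = 0.646), and for pancreas and erythrocytes none of the members was.

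In all, 1575 genes were higher and 932 lower in the jejunum, of which 491 and 233 at least 2-fold. Genes higher were 1023 with a stromal covariate, and genes lower 1651 with array weights. The percentage higher was 62.8, against 52 after quantile normalization and 50.5 after centring each array on its median. No fold is given where a group mean lay below 4.91, the level filter, since such a mean was not told from background here and the log2 difference depends on it. Such means were, among others, those of Fabp6 (4.4 ± 0.47) and Slc10a2 (4.45 ± 0.68) in the wild-type jejunum, and of Fabp1 (3.76 ± 0.27) and Lct (4.72 ± 0.11) in the wild-type ileum, where those of Cyp2b10, Reg1, Slc2a2, Slc2a7, Cd36 and Pdk4 were below it as well.

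The cKI ileum had less signal of some ileal genes, bile acid carriers among them, and more of a few jejunal genes. Gata4 was at 8.21 ± 0.21 in the cKI ileum and 6.82 ± 0.36 in the control ileum, a difference of 1.38 ± 0.185 (2.61-fold, adjusted p = 0.00453), higher in 3 of 3 cKI arrays. Fabp6 was lower, with a difference of -1.75 ± 0.24 (3.35-fold, adjusted p = 0.00499). Suox, sulfite oxidase, an ileum-high gene, differed by -1.82 ± 0.151 (3.53-fold, adjusted p = 3.57e-05). Rragd, a GTPase of amino acid sensing that is high in jejunum, was higher by 1.14 ± 0.16 (2.21-fold, adjusted p = 0.00547). The comparison asks what Gata4 does when expressed in the ileum. The Gata4 call was lost in a fit of the 6 arrays alone (adjusted p = 0.0524) and without variance moderation (0.0559).

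Other genes with ileal expression fell as well. Slc10a2 differed by -1.7 ± 0.291 (adjusted p = 0.016), with 0.0506 without control ileum replicate 3 and 0.0618 without cKI ileum replicate 3. Slc13a1, a sulfate transporter, differed by -1.86 ± 0.257 (adjusted p = 0.00499), Slc25a48, a mitochondrial carrier, by -1.86 ± 0.268 (0.00652), and Rnf180, a ubiquitin ligase, by -1.47 ± 0.123 (3.57e-05). In bile acid uptake 2 of 11 genes were lower (7 adjusted over the list alone, camera adjusted p = 2.95e-08), and only this list of the 15 called held with an estimated correlation (adjusted p = 0.03573). Slc51a, a basolateral bile acid exporter, differed by -0.74 ± 0.187 (adjusted p = 0.0878), and Cubn, the cobalamin receptor, by -2.09 ± 0.473 (0.0594, and 0.019 with a replicate block within sets of mice or 0.0298 with one over all arrays). Without control ileum replicate 3 the Cubn value was 0.0424, and without cKI ileum replicate 2 it was 0.0443. Ileal textbook markers had 2 of 18 lower (10 adjusted over the list alone; 4.88e-11, and adjusted p = 0.1578 with an estimated correlation). In cobalamin uptake 0 of 7 passed (1 lower adjusted over the list alone; 0.114).

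Few jejunal genes were called higher in the cKI ileum. Lct was at 8.79 ± 1.34 in cKI and 5.99 ± 0.83 in control arrays, higher by 2.79 ± 0.596 (adjusted p = 0.0475). Its adjusted p was 0.0843 without control ileum replicate 1, 0.129 without control ileum replicate 3, 0.151 without cKI ileum replicate 1 and 0.0959 without cKI ileum replicate 2. Lmcd1, a LIM protein that binds GATA6, was higher by 1.05 ± 0.159 (0.00899). Ugt2a3, a glucuronosyltransferase, was higher by 1.75 ± 0.281 (0.0142), and 0.0701 without cKI ileum replicate 1. Fabp1 differed by 2.59 ± 0.645 (adjusted p = 0.0855) and 0.0431 without cKI ileum replicate 3, and Cd36 by 1.52 ± 0.365 (0.0729) and 0.0205 without control ileum replicate 2, or 0.0353 with the block within sets. Jejunal textbook markers had 1 of 17 higher (3 adjusted over the list alone, camera adjusted p = 0.0455, and adjusted p = 0.6556 with an estimated correlation). That call was lost without control ileum replicates 1 (0.0888) or 3 (0.0938) and without cKI ileum replicates 1 (0.11) or 2 (0.438). Sugar digestion had 1 of 15 higher (1 adjusted over the list alone; 0.805) and lipid absorption 0 of 24 (2 higher adjusted over the list alone; 0.575). Both were called higher without cKI ileum replicate 3 (0.023 and 0.000417).

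Single genes of metal binding, sterol synthesis and goblet cells were called as well. Mt1, which binds zinc, was higher by 2.01 ± 0.179 (4.02-fold, adjusted p = 5.66e-05). Hmgcs1, of the mevalonate pathway, differed by -0.74 ± 0.121 (0.0145), and 0.0701 without cKI ileum replicate 1. In cholesterol synthesis 2 of 20 were lower (7 adjusted over the list alone, camera adjusted p = 2.95e-08, and adjusted p = 0.187 with an estimated correlation). Clca1, a goblet cell metalloprotease, differed by -0.74 ± 0.118 (0.0141), and Muc2, the gel-forming mucin, by -0.53 ± 0.119 (0.0589, and 0.031 with a replicate block over all arrays). The goblet list had 1 of 16 lower (2 adjusted over the list alone; 1.11e-05, and adjusted p = 0.1578 with an estimated correlation). In proliferation 0 of 23 genes passed, with a median of 0.33, or 0.18 without control ileum replicate 2 (4.68e-05, and adjusted p = 0.5286 with an estimated correlation). With a stromal covariate the proliferation median was 0.05 and the list was not called (camera adjusted p = 0.462). In the stem cell list 0 of 17 passed, with a median of 0.21 (0.00807, and adjusted p = 0.3023 with an estimated correlation). Amino acid uptake had 0 of 19 (3 higher and 3 lower adjusted over the list alone; median -0.26; 0.041, and adjusted p = 0.7547 with an estimated correlation). Its call was lost without control ileum replicates 1 (0.254) or 2 (0.117) and cKI ileum replicate 3 (0.867).

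Lists of non-epithelial cells were called lower in the cKI ileum at the preset correlation, and none of them with an estimated one. Pdgfrb, a receptor of mesenchymal cells, differed by -0.78 ± 0.132 (adjusted p = 0.0158). It was 0.0569 without control ileum replicate 2, 0.0701 without cKI ileum replicate 1 and 0.0613 without cKI ileum replicate 3. Stromal genes had 2 of 14 lower (10 adjusted over the list alone, camera adjusted p = 4.85e-09, and adjusted p = 0.1948 with an estimated correlation). T and NK cell genes had 0 of 11 (10 lower adjusted over the list alone; median -1.19; 7.65e-10, and adjusted p = 0.187 with an estimated correlation), and Cd8a, a T cell coreceptor, differed by -1.17 ± 0.348 (adjusted p = 0.142, and 0.0281 with a replicate block within sets of mice). Interferon genes had 0 of 19 (12 lower adjusted over the list alone; median -0.75, or -0.45 without control ileum replicate 2; 6.07e-11, and adjusted p = 0.187 with an estimated correlation), with Irf7, an interferon regulator, at -1.24 ± 0.366 (adjusted p = 0.142, and 0.0155 with that block). Class II genes had 2 of 6 lower (4 adjusted over the list alone; 2.22e-05, and adjusted p = 0.187 with an estimated correlation). B and plasma cells had 1 of 8 lower (1 adjusted over the list alone; 2.88e-05, and adjusted p = 0.1977 with an estimated correlation). Isolation stress genes had 0 of 16 (median -0.37, or -0.19 without control ileum replicate 2; 0.000246, and adjusted p = 0.3384 with an estimated correlation). Myeloid genes had 0 of 10 (median -0.3; 0.0237, and adjusted p = 0.2926 with an estimated correlation), with 0.18 without control ileum replicate 2 and 0.0505 without control ileum replicate 3.

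In the cKI comparison 40 genes were higher and 50 lower, of which 10 and 21 at least 2-fold, and 1804 had an unadjusted limma p below 0.05. Genes higher were 16 and 6 without control ileum replicates 2 and 3, and 7, 21 and 16 without cKI ileum replicates 1, 2 and 3. Genes lower were 141, 26 and 33 without control ileum replicates 1, 2 and 3, and 13 and 22 without cKI ileum replicates 1 and 3. These counts moved widely with the settings: 388 higher and 378 lower with array weights, 1 and 5 without moderation, 7 and 12 in the 6 arrays alone, 6 and 6 with a stromal covariate, and 19 and 33 without a level filter. Genes higher were 23 with a replicate block over all arrays and 23 after centring. The percentage higher was 44.4, against 34.8 after quantile normalization and 26.4 after centring. Of the 13 lists not called, 6 had a median or mean that differed in sign from the camera direction, which was down: GATA factors (median -0.07, mean 0.02; 0.65), iron (0.01, -0.05; 0.65), retinoid (mean 0.06; 0.794), drug metabolism (0.02, -0.04; 0.65), antimicrobial (0.02, 0.12; 0.65) and enteroendocrine (-0.03, 0.01; 0.65). Calcium and vitamin D (0.0586), fatty acid oxidation (0.5), Paneth (0.375) and tuft cells (0.145) had a negative median. Without control ileum replicate 3, calcium and vitamin D was called (0.0278, and 0.0498 with the block over all arrays), and without control ileum replicate 2 the antimicrobial list was (0.0336).

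**Figure D1:**
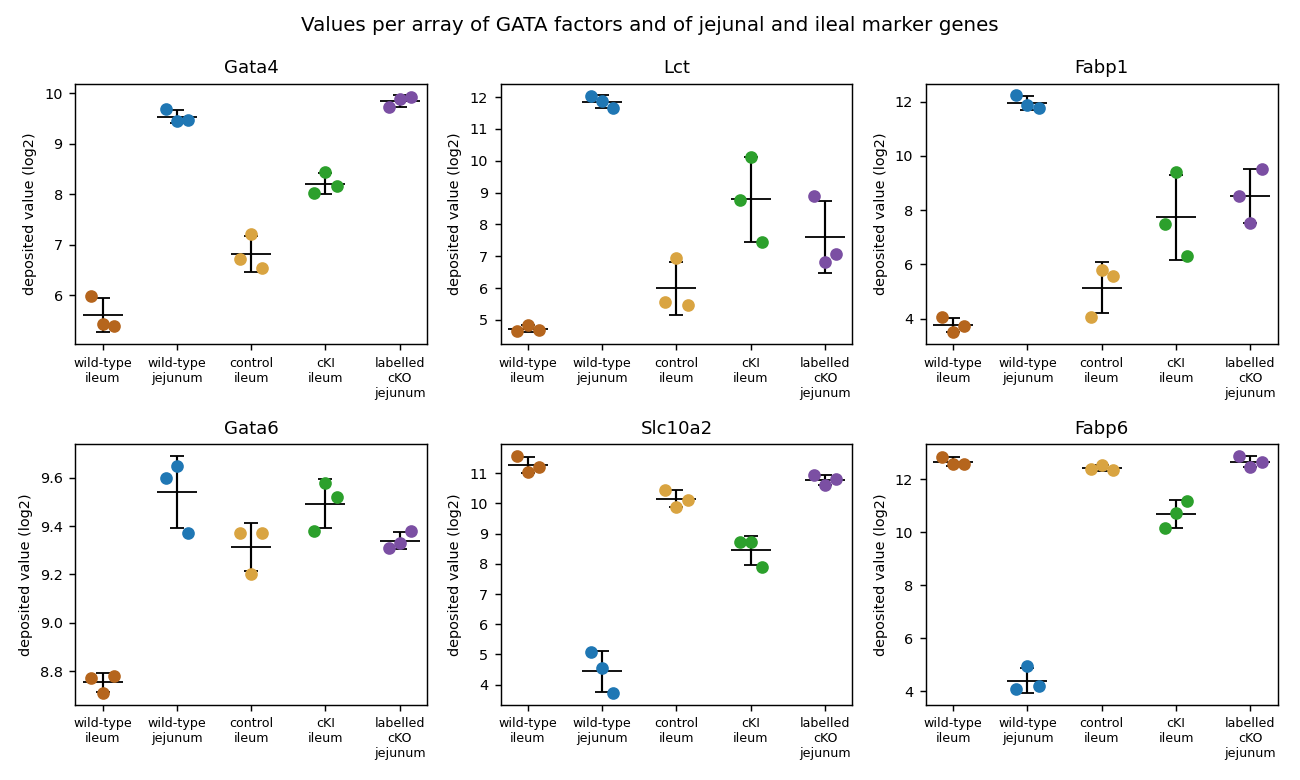
Deposited log2 value (y axis) of Gata4, Gata6, Lct, Fabp1, Slc10a2 and Fabp6 in each of the 15 arrays, by group (points are arrays, lines are group means with SD, n = 3). Gata4 was between 9.72 and 9.93 in the arrays labelled cKO, and between 9.45 and 9.68 in the wild-type jejunum.

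Jejunum labelled cKO had more signal of ileal bile acid genes and less of many jejunal genes than wild-type jejunum. Fabp6 was at 12.67 ± 0.21 against 4.4 ± 0.47 in the wild-type jejunum, higher by 8.27 ± 0.24 (adjusted p = 2.67e-11). Slc10a2 was higher by 6.34 ± 0.291 (adjusted p = 4.51e-09). Cyp2b10 differed by -6.82 ± 0.33 (adjusted p = 5.54e-09), and Cd36 by -4.87 ± 0.365 (adjusted p = 6.73e-07), with no fold given since 1 mean of each of these 4 lay below 4.91. Lct differed by -4.26 ± 0.596 (19.2-fold, adjusted p = 0.000224). The comparison asks what loss of Gata4 does in the jejunum. With no jejunal control from the cKO mice among these arrays, the genotype and the set of mice cannot be told apart in it.

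Gata4 signal was not lower in the arrays labelled cKO. It was at 9.84 ± 0.11 against 9.53 ± 0.13, a difference of 0.31 ± 0.185 (95% interval -0.08 to 0.71, adjusted p = 0.322), higher in 3 of 3 arrays. After subtraction of the difference between control and wild-type ileum it was -0.91 (adjusted p = 0.0199). That value holds only if the cKO mice share this difference, which is not known. Positions of the probes relative to the deleted part of the gene were not given in the sources used here. Gata6 differed by -0.2 ± 0.0997 (adjusted p = 0.233) and Gata5 by 0.23 ± 0.181 (0.473). Osr2, a zinc finger factor of the ileum, and Foxa1 were higher by 1.33 ± 0.156 and 1.23 ± 0.122, and Zfpm1 differed by -0.67 ± 0.142. Of the GATA and intestinal factors 3 were higher, 2 lower and 15 not passed (3 and 2 adjusted over the list alone, camera adjusted p = 0.0201, and adjusted p = 0.3652 with an estimated correlation). The list was not called without wild-type jejunum replicate 3 (0.052) or cKO jejunum replicate 1 (0.0759).

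Genes that recover or sense bile acids rose in the arrays labelled cKO. Nr1h4 was higher by 1.29 ± 0.159 and Slc51a by 1.6 ± 0.187. In bile acid uptake 8 of 11 genes were higher (8 adjusted over the list alone, camera adjusted p = 3.83e-12, and adjusted p = 0.006728 with an estimated correlation). Ileal textbook markers had 11 higher, 1 lower and 6 not passed (13 and 1 adjusted over the list alone; 2.47e-11, and adjusted p = 0.08851 with an estimated correlation). Suox was higher by 4.51 ± 0.151 and Slc6a14, a broad amino acid carrier, by 6.08 ± 0.711. Mvd and Sqle, both of sterol synthesis, were higher by 1.27 ± 0.144 and 1.69 ± 0.166. In cholesterol synthesis 15 of 20 were higher (15 adjusted over the list alone; 2.17e-17, and adjusted p = 0.05004 with an estimated correlation). Creb3l1, a secretory cell factor, was higher by 1.07 ± 0.11, with 9 of 16 goblet genes higher (12 adjusted over the list alone; 3.19e-10, and adjusted p = 0.03406 with an estimated correlation). Cldn2, a tight junction pore, was higher by 1.35 ± 0.143 (calcium list 4 higher, 1 lower of 8; 4 and 1 adjusted over the list alone; 0.00763, and adjusted p = 0.1871 with an estimated correlation).

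Some of the genes of jejunal digestion and absorption fell, and their lists were called at the preset correlation only. Slc2a7 differed by -2.41 ± 0.295 and Slc37a4, the glucose 6-phosphate carrier, by -1.14 ± 0.129. In sugar digestion 7 of 15 were lower (11 adjusted over the list alone, camera adjusted p = 6.59e-07, and adjusted p = 0.3385 with an estimated correlation). Acsl5, which activates fatty acids, differed by -1.08 ± 0.186, with 12 of 24 lipid absorption genes lower (13 adjusted over the list alone; 2.48e-07, and adjusted p = 0.3652 with an estimated correlation). Pdk4 differed by -1.84 ± 0.254, with 7 lower and 1 higher of 17 fatty acid oxidation genes (10 and 1 adjusted over the list alone; 0.000615, and adjusted p = 0.3536 with an estimated correlation). Lrat, which esterifies retinol, differed by -2.1 ± 0.179, with 5 of 12 retinoid genes lower (7 adjusted over the list alone; 0.00119, and adjusted p = 0.1425 with an estimated correlation). Jejunal textbook markers had 9 lower and 1 higher of 17 (9 and 1 adjusted over the list alone; 7.76e-06, and adjusted p = 0.3385 with an estimated correlation). Drug metabolism had 7 lower, 4 higher and 16 not passed (8 and 5 adjusted over the list alone; 0.0432, and adjusted p = 0.6351 with an estimated correlation). Its call was lost without wild-type jejunum replicates 1 (0.057) or 2 (0.0508) and cKO jejunum replicates 2 (0.202) or 3 (0.0613).

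Lists of other cell types were called in the arrays labelled cKO as well. Ghrl, the ghrelin gene, was higher by 1.87 ± 0.206, with 4 enteroendocrine genes higher, 2 lower and 13 not passed (5 and 2 adjusted over the list alone, camera adjusted p = 0.022, and adjusted p = 0.5461 with an estimated correlation). That list was not called without wild-type jejunum replicate 3 (0.096) or cKO jejunum replicate 2 (0.0511). After subtraction of the difference between control and wild-type ileum its camera direction was reversed (median -0.15), and it was not called. Axin2, a Wnt target, was higher by 0.66 ± 0.142, with 3 stem cell genes higher and 1 lower of 17 (7 and 1 adjusted over the list alone; 0.0101, and adjusted p = 0.3652 with an estimated correlation; 0.0621 without cKO jejunum replicate 2). H2-Aa was higher by 0.99 ± 0.204, with 2 of 6 class II genes higher (2 adjusted over the list alone). The class II list had a camera adjusted p of 0.0201, or 0.479 with an estimated correlation, and 0.127 without cKO jejunum replicate 1. The subtraction reversed its camera direction too (median -0.27), and it was then not called. Interferon genes had 0 of 19 (median -0.54; 0.0306, and adjusted p = 0.656 with an estimated correlation), with 0.335 without wild-type jejunum replicate 3 and 0.181 without cKO jejunum replicate 2. Stromal genes had 1 of 14 higher (1 adjusted over the list alone; 0.0137, and adjusted p = 0.6243 with an estimated correlation; 0.057 without cKO jejunum replicate 1).

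In total 609 genes were higher and 901 lower in the arrays labelled cKO, of which 150 and 239 at least 2-fold. After subtraction of the difference between control and wild-type ileum, 900 were higher and 2070 lower, and 10 lists were called in place of 17. Genes lower were 566 with only the 6 arrays. Genes lower were 542 without wild-type jejunum replicate 1 and 548 without replicate 2 of that group. The percentage higher was 40.3, against 51.2 after quantile normalization and 48.8 after centring. Lists not called were iron (0.169), Paneth (0.541), proliferation (0.151), antimicrobial (0.104), T and NK (0.289) and B and plasma cells (0.63). Proliferation and amino acid uptake (0.232) were called without cKO jejunum replicate 1 (0.000661 and 0.026). In cobalamin (median -0.05, mean 0.18; 0.553) and myeloid genes (-0.02, 0.07; 0.478) the median was below 0 and camera up, and in tuft cells (0.07, -0.04; 0.889) and isolation stress genes (mean -0.05; 0.889) the mean was below 0 and camera up.

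Of the genes called in the cKI ileum, many differed in the opposite direction in the arrays labelled cKO. Rragd and Lmcd1 were higher in the cKI ileum and lower in the arrays labelled cKO, where they differed by -2.18 ± 0.16 and -1.09 ± 0.159. Fabp6, Suox and Rnf180 showed the reverse. Il33, an epithelial alarmin, Gstm6, a glutathione transferase, and Hsd17b6, a steroid dehydrogenase, followed Rragd, but lost their cKI call in each of 6 runs without 1 cKI or control array, with the highest adjusted p at 0.0904, 0.0846 and 0.13 (without control ileum replicate 2, cKI ileum replicate 3 and control ileum replicate 2). With a replicate block within sets of mice Hsd17b6 was at 0.0732, and with one over all arrays it and Il33 were at 0.0591. Of 90 genes called in the cKI, 52 were called in the opposite direction in the cKO, against 5.64 if calls were independent, and 3 in the same direction. The 52 became 32 and 29 without wild-type jejunum replicates 1 and 2, 32 and 20 without control ileum replicates 2 and 3, and 13 and 32 without cKI ileum replicates 1 and 3. They were 236 with array weights, 30 without a level filter, 12 with only the 6 arrays of each comparison, 10 with a stromal covariate and 5 without moderation. In 51 of the 52 the knockin moved toward the jejunal level, 19 of them jejunal and 32 ileal genes. The other 35 were not called in the cKO comparison. Across genes, which are not independent replicates, the jejunum minus ileum and the cKI minus control differences correlated with r = 0.312 (rho = 0.238). Those of cKI and cKO correlated with r = -0.329 (rho = -0.244). Neither pair shares a group of arrays.

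Of 724 genes called at least 2-fold between wild-type jejunum and ileum, 41 (5.66%) were called toward the jejunum in the cKI ileum and 2 away from it. In the arrays labelled cKO 495 (68.4%) were called toward the ileum and 1 away from it. The median gene moved by 12.6% of its regional difference in the cKI and by 60.2% in the cKO. Between control and wild-type ileum, a background without a named transgene, 199 (27.5%) were called toward the jejunum and 27 away from it, and the median gene moved by 16.5%. In simulated groups equal to the wild type of their region these 3 medians were -0.128%, 2.44% and 2.59% on average, and at most 1.68%, 4.05% and 3.91%. These show what choosing the genes on shared arrays gives. Whether they cover the spread between real arrays was not tested. Of ileum-high genes 24 (10.3%) were called in the cKI, and of jejunum-high genes 17 (3.46%), such as Fabp6 against Rragd. The 5.66% became 2.49% without control ileum replicate 3 and 1.95% without cKI ileum replicate 1. It was 20.5% with array weights, 1.64% with only the 6 arrays, 1.3% with a stromal covariate, 0.588% without moderation and 2.47% for regional genes without a fold minimum. With an estimated correlation the fall of ileum-high genes in the cKI had a camera adjusted p of 0.000159, and the rise of jejunum-high genes 0.554. Toward the ileum, the cKO had 0.00552 for jejunum-high and 3e-06 for ileum-high genes. The cKO and regional differences share the wild-type jejunum arrays: across genes they correlated with r = -0.797 (rho = -0.695), where simulated differences without any effect gave -0.5. Their covariance was -0.232, against -0.0171 in those simulated differences, so the shared arrays gave a small part of it.

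**Figure D2:**
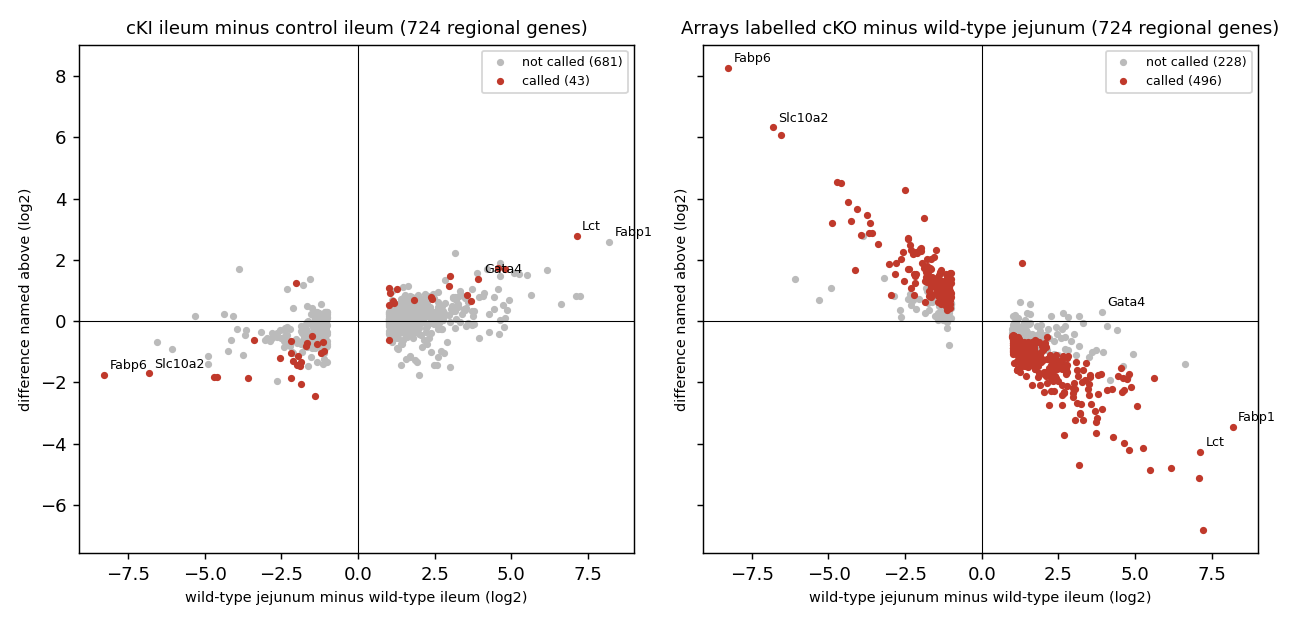
Log2 differences of single genes: jejunum minus ileum on the x axis, and cKI minus control or cKO minus wild-type jejunum on the y axis (points are genes at least 2-fold apart between regions). Across all genes tested the correlations were 0.312 for the cKI and -0.797 for the cKO. The second has the wild-type jejunum arrays in both differences (covariance -0.232, against -0.0171 in simulated differences without any effect).

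A regional index over these genes was set at 0 for the wild-type ileum and 1 for the wild-type jejunum. It was 0.177 ± 0.075 (SD) in the control ileum, 0.334 ± 0.066 in the cKI ileum and 0.377 ± 0.068 in the arrays labelled cKO. Over textbook genes such as Fabp6 and Fabp1 alone, it was 0.067 ± 0.046, 0.336 ± 0.085 and 0.284 ± 0.042. The regional genes were chosen on the wild-type arrays that set the scale, and the textbook genes were not. For cKI against control the difference was 0.157, and for cKO against wild-type jejunum -0.623, each with a two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow. The cKI difference came mostly from ileum-high genes. Their index alone differed by 0.248 (exact permutation p = 0.1), and that of jejunum-high genes alone by 0.074 (exact permutation p = 0.6).

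**Figure D3:**
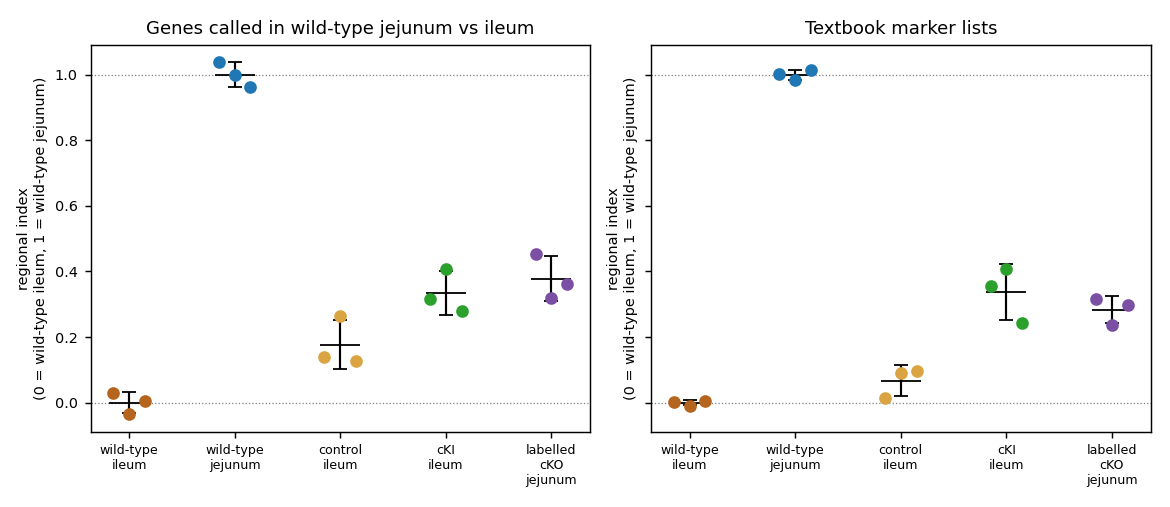
Regional index by array (points) and group mean with SD (n = 3), without unit, with the wild-type ileum at 0 and the wild-type jejunum at 1. The group mean was 0.334 in the cKI ileum, 0.177 in the control ileum and 0.377 in the arrays labelled cKO.

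Control and wild-type ileum differed widely without a Gata4 transgene being named in either. Terc, the telomerase RNA, was higher in the control ileum by 2.66 ± 0.104 (6.31-fold, adjusted p = 9.79e-10), and Cks2, a cyclin-dependent kinase subunit, by 2.56 ± 0.168 (1.48e-07). Car1, a carbonic anhydrase, differed by -5.09 ± 0.34 (1.64e-07), and Snord22, a small nucleolar RNA, by -5.5 ± 0.199 (6.13e-10). Gata4 was higher by 1.22 ± 0.185 (2.33-fold, adjusted p = 0.000284) and Gata6 by 0.56 ± 0.0997 (0.000929). Gip was higher by 2.41 ± 0.311 and Dgat1, which makes triglycerides, by 1.49 ± 0.145. This comparison measures the background between the sets of mice: 2275 genes were higher and 1015 lower, 277 and 107 of them at least 2-fold. The mice, their strain, the RNA preparation and any array batch cannot be told apart in it. Genes lower were 1616 with array weights, 1779 after quantile normalization and 1727 after centring, and genes higher 1500 after centring. The percentage higher was 69.1, against 47.9 after quantile normalization and 46.5 after centring. The median difference of all genes was 0.085, against -0.024 after quantile normalization and -0.036 after centring. Across genes these differences and those of jejunum minus ileum, which share the wild-type ileum arrays, had a covariance of 0.0739, against 0.0172 in simulated differences without any effect, and correlated with r = 0.258 (rho = 0.222), against 0.499.

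Of the 28 lists 2 were called in that background, against 6, 1 and 8 without wild-type ileum replicates 1 and 3 and control ileum replicate 1, and 1 without control ileum replicate 2. They were 5 without a level filter, 6 with a replicate block within sets of mice, 1 with a stromal covariate, and 0 with array weights, the 6 arrays alone, the 75th percentile filter or the mean over clusters. Interferon genes had 8 of 19 higher (8 adjusted over the list alone, camera adjusted p = 0.0412, and adjusted p = 0.9615 with an estimated correlation), among them Ifit1 (1.66 ± 0.374). Enteroendocrine genes had 6 of 19 higher (10 adjusted over the list alone; 0.0412, and adjusted p = 0.9615 with an estimated correlation), among them Cck, of I cells (1.17 ± 0.197). The first was not called without wild-type ileum replicates 2 (0.0725) or 3 (0.0801) or control ileum replicate 2 (0.254), and the second without wild-type ileum replicate 2 (0.0612) or control ileum replicate 2 (0.235). In bile acid (median 0.07), iron (0.2), calcium (0.06), tuft (0.09) and isolation stress genes (0.14) the camera direction was down.

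**Figure D4:**
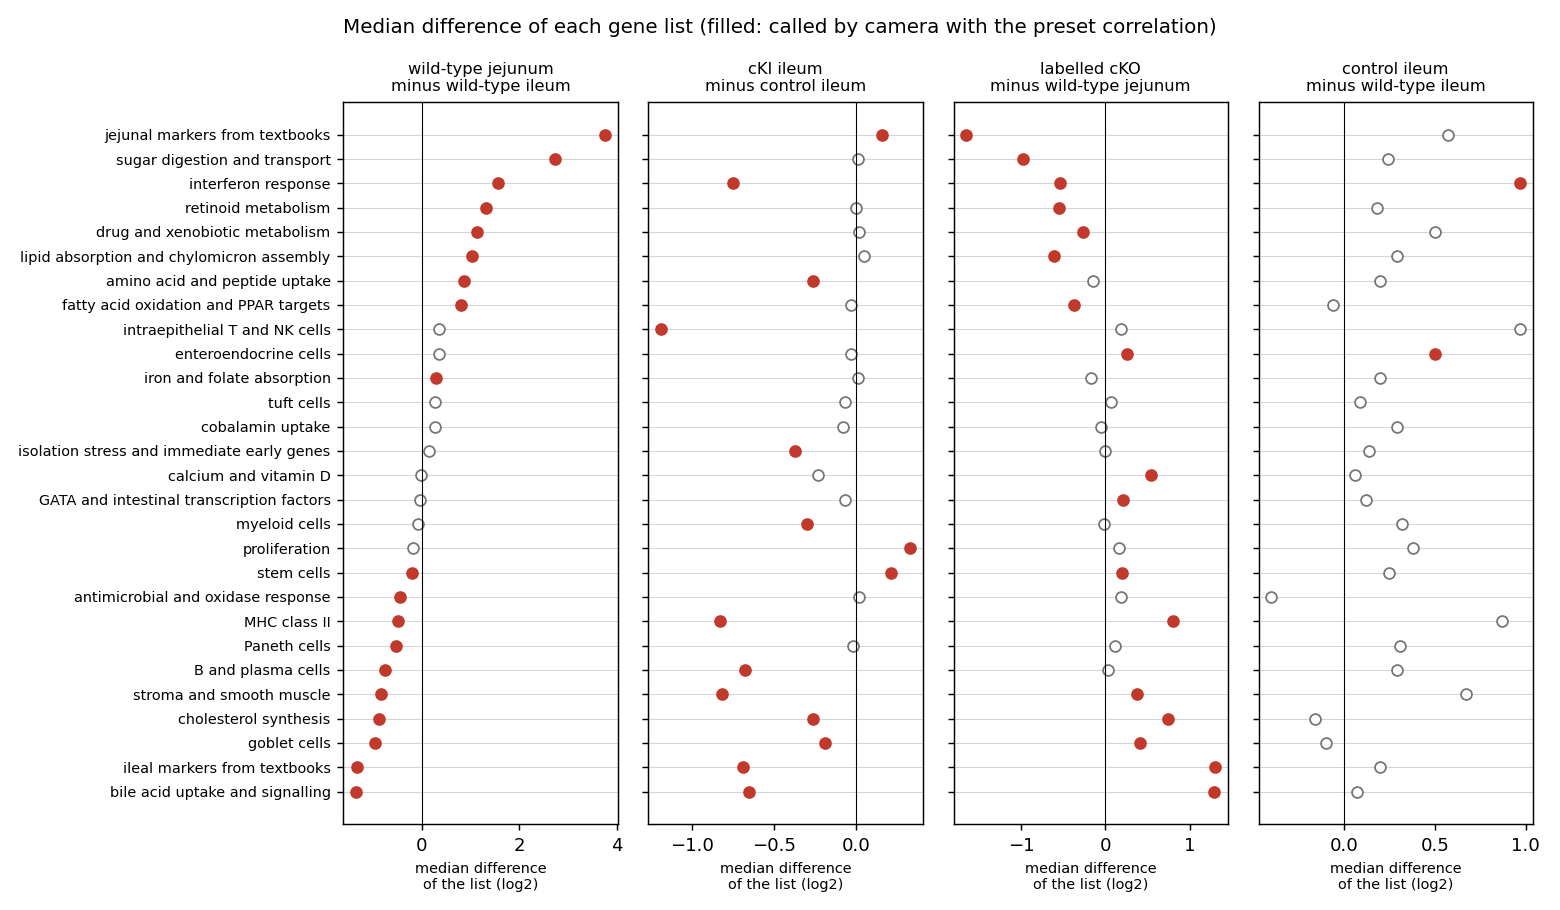
Median log2 difference of each gene list (y axis) on a log2 x axis, with a panel per comparison and filled points for lists called by camera with the preset correlation. Bile acid uptake had a median of -0.65 in the cKI ileum and 1.29 in the arrays labelled cKO.

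Both altered tissues differed from the wild-type region they moved toward, in comparisons across sets of mice. Gata4 in the cKI ileum differed by -1.33 from the wild-type jejunum (2.51-fold, adjusted p = 6.64e-05), and 4924 genes differed. In the arrays labelled cKO it was higher than in the wild-type ileum by 4.24 (18.9-fold, adjusted p = 8.89e-09), and 601 genes differed, 384 higher and 217 lower. That count was 279 without wild-type ileum replicate 2 and 372 without replicate 3 of that group, 299 with only the 6 arrays and 377 without moderation. Region and set of mice are mixed in both comparisons, and 3290 genes differed between control and wild-type ileum. The counts therefore do not show whether either tissue reached that region.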

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

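The tests of the Gata4 signal and of non-epithelial cells, and the index test of the set of mice, were chosen after the result was seen.

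Transcript clusters outside the gene counts also differed between groups, a signal in data that no comparison of genes used. Of 872 tested clusters with several symbols, 95 were called between wild-type jejunum and ileum, 49 between the arrays labelled cKO and wild-type jejunum, and 359 between control and wild-type ileum. Of 5699 tested clusters without a symbol in the annotation used here, 212, 137 and 1778 were called in these comparisons. In cKI against control ileum 0 of both kinds were called by limma, and 153 and 453 had an unadjusted p below 0.05. No explanation was tested for these.

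Gata4 signal was not lower in the arrays labelled cKO, although Fabp6 and Slc10a2 had moved to ileal levels. Unmodified wild-type jejunum was argued against: the highest textbook index of an array labelled cKO was 0.316, and the lowest of a wild-type jejunum array was 0.984. By Gata4 alone, ileal tissue as 1 part in 2 stays open: such a share would give -0.91, below the lower 95% bound of the Gata4 difference, -0.08. With the set difference subtracted Gata4 was at -0.91 as well (adjusted p = 0.0199, 95% interval -1.47 to -0.35). The subtraction takes the cKO mice to share that difference, which is not known. A share of 1 part in 2 lowers no gene by more than 1 on the log2 scale, and the 17 jejunal textbook markers differed by -1.84 on average. That argues against this share as the only source of the shift, and a larger share would lower Gata4 further. That the Gata4 probe set reads a part of the transcript kept after the deletion is a candidate explanation that stays open: the difference was 0.31, and the probe positions were not given in the sources used here. A change of Gata4 protein with the transcript kept was not tested.

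Differences between the arrays labelled cKO and wild-type jejunum mix the genotype with the set of mice. The set difference measured between control and wild-type ileum did not point toward the ileum, with an index of the control ileum of 0.177 ± 0.075 (SD), or 0.067 ± 0.046 over textbook genes (0.014 in replicate 1). Whether the cKO mice share that difference is not known, since their mean of small nucleolar RNAs was 8.06, against 7.02 in the control and 8.24 in the wild-type jejunum, so a set difference of their own stays open. For the 361 cKO calls that were not called between regions the set of mice stays open: 64 were called the same way between control and wild-type ileum and 50 the opposite way. Genes lower in both were 28 against 16.3 if independent (Fisher's exact p = 0.00329), and genes higher in both 36 against 30 (0.13).

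Lists of stromal, lymphocyte, MHC class II and interferon genes were called lower in the cKI ileum than in its control at the preset correlation only (0.187 to 0.1977 with an estimated one), and 0 of 11 T and NK and 0 of 19 interferon genes passed. With the mean of stromal markers as a covariate, the median of the T and NK cell list moved from -1.19 to -0.52 and B cell genes from -0.68 to -0.03, which is consistent with fewer non-epithelial cells in the cKI preparations. With the covariate the T and NK (camera adjusted p = 0.00206), class II (-0.56, 0.0106) and interferon lists (-0.27, 0.0115) were still called lower at the preset correlation, but not with an estimated one (0.6132, 0.6132 and 0.6721). Control ileum replicate 2 gave part of the signal. Without it the median of stromal genes went from -0.82 to -0.5, of interferon genes from -0.75 to -0.45 and of B and plasma cells from -0.68 to -0.44. The T and NK median was -1 without it (camera adjusted p = 5.03e-08 at the preset correlation). That setting also called up to 17 lists in other splits of these arrays, so whether replicate 2 was the only source stays open. In the T and NK and interferon lists each control array lay above each cKI array. In the stromal, B and plasma and class II lists control ileum replicate 1 (5.64, 5.01 and 8.43) lay below cKI ileum replicate 2 (5.75, 5.17 and 8.52). Cells that follow the stromal markers, as the only source of the lower ileum-high genes, were argued against for those genes as a set. Their median was -0.4 without and -0.48 with the covariate. The covariate left part of the lymphocyte and class II signal, so other non-epithelial cells were not tested by it. For ileal textbook markers non-epithelial cells stay open in part. That median went from -0.69 to -0.54, called at the preset correlation (camera adjusted p = 3.88e-08) but not with an estimated one (0.28). A change of immune cells caused by Gata4 stays open and was not tested, and abundant markers in control ileum replicate 2 were Jchain (9.14), Acta2 (9.02), Vim (8.41) and Cd3e (8.2).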

How the results depend on the processing

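The replicate block within each set of mice and the stromal covariate were chosen after the result was seen.

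Regional and cKO gene calls held more firmly than the cKI ones, apart from the subtraction of the set difference in the cKO. For list calls the cKO was not firmer throughout. Array weights ended 4 of 17 list calls in the cKO and 1 of 15 in the cKI. The stromal covariate ended 4 in the cKO. In the cKI it ended 4 and reversed the camera direction of 2 more, which were then not called. Quantile normalization ended 0 and 2. The call and direction of Gata4 between regions, the regional genes moved in the cKO and the regional indices kept their side under every alternative that was run for them. Signal over background limits genes below the level filter of 4.91.

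A level filter left out raises the number of genes tested, and a fit of only the 6 arrays compared lowers the number of arrays behind each variance. Without a level filter, 19 genes were higher and 33 lower in the cKI ileum (49 of the 52 were among the 90), 30 genes were opposite in cKI and cKO, and 5 lists were called in control against wild-type ileum. With only the 6 arrays compared, 7 were higher and 12 lower, 566 were lower in the cKO, 299 differed between cKO jejunum and wild-type ileum, 1.64% of regional genes moved in the cKI, 12 genes were opposite, Gata4 in the cKI was 1.38 (adjusted p = 0.0524) and 0 lists were called in control against wild-type ileum. Without moderation, for which the cause was not tested, 1 was higher and 5 lower in the cKI, 377 differed between cKO jejunum and wild-type ileum, 0.588% of regional genes moved in the cKI, 5 genes were opposite and Gata4 in the cKI was 1.38 (0.0559). The cKI call of Gata4 was lost in these 2 settings and in no other that was run. Of the 33 named cKI calls, 9 were lost without a level filter, 25 with the 6 arrays and 31 without moderation.

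For the following settings the cause was not tested. Array weights gave 1651 lower in the jejunum, 388 higher and 378 lower in the cKI, 1616 lower in control against wild-type ileum, 20.5% of regional genes moved in the cKI, 236 opposite genes and 0 lists in control against wild-type ileum. Quantile normalization gave 1779 lower in control against wild-type ileum. Centring gave 1500 higher and 1727 lower there and 23 higher in the cKI. The 75th percentile filter and the mean over clusters gave 0 lists in control against wild-type ileum. A replicate block over all arrays gave 23 higher in the cKI, and one within sets gave 6 lists in control against wild-type ileum. Of the named genes, 33 of them called in the cKI, the first block ended 6 cKI calls and brought 4, and the second ended 3 and brought 8. The blocks moved no other count in the text beyond 1.5 times.

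With the stromal covariate, 1023 genes were higher in the jejunum, 6 higher and 6 lower in the cKI, 1.3% of regional genes moved in the cKI, 10 genes were opposite, and 1 list was called in control against wild-type ileum. In the cKI the isolation stress list then had a median of -0.04 and the myeloid list of 0.05, both with a reversed camera direction and not called. The proliferation list had 0.05 and was not called either (camera adjusted p = 0.462), the stromal list itself had 0.05, and 28 of the 33 named cKI calls were lost. With the covariate the cKI median of ileum-high genes went from -0.4 to -0.48 and that of jejunum-high genes from 0.13 to 0.2. These grew in size, while the medians of the lists just named shrank. Why the named calls were lost was not tested.

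A minimum of 2-fold left 491 higher and 233 lower in the jejunum, 10 and 21 in the cKI, 150 and 239 in the cKO, 277 and 107 in control against wild-type ileum, and 20 opposite. Subtraction of the set difference gave 2070 lower in the cKO, Gata4 at -0.91 (adjusted p = 0.0199) and 10 lists. Enteroendocrine (-0.15) and MHC class II genes (-0.27) were then reversed in direction and not called. Of regional genes without a fold minimum, 2.47% were called toward the jejunum in the cKI. The index over textbook lists gave 0.269 for the cKI and -0.716 for the cKO. With an estimated correlation 1, 1, 2 and 0 lists were called in the regional, cKI, cKO and control comparisons.

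With each array left out in turn, genes higher in the jejunum ranged from 1121 to 1594 and lower from 692 to 777. In the cKI 6 (without control ileum replicate 3) to 35 were higher and 13 (without cKI ileum replicate 1) to 141 (without control ileum replicate 1) lower. In the cKO 442 to 632 were higher and 542 (without wild-type jejunum replicate 1) to 988 lower, and in control against wild-type ileum 1681 to 1941 and 740 to 886. Between cKI ileum and wild-type jejunum 3877 to 4627 differed, and between cKO jejunum and wild-type ileum 279 (without wild-type ileum replicate 2) to 592. Regional genes moved ranged from 1.95% (without cKI ileum replicate 1) to 5.91% in the cKI and from 57.1% to 72.9% in the cKO, and opposite genes from 13 (without cKI ileum replicate 1) to 67. Gata4 ranged from 3.82 to 4.12 between regions, 1.24 to 1.58 in the cKI and 0.27 to 0.38 in the cKO. The index difference ranged from 0.117 to 0.203 in the cKI and from -0.665 to -0.597 in the cKO. Lists called ranged from 17 to 20, 13 to 16, 13 to 16, and 1 (without wild-type ileum replicate 3) to 8 (without control ileum replicate 1) in the same order. The amino acid list in the cKI ranged from -0.43 to -0.1, and was reversed in its camera direction without cKI ileum replicate 3 (-0.1).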

Other observations

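The test of the gap between ileum-high and jejunum-high genes was chosen after the result was seen.

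Small nucleolar RNAs, which guide the modification of ribosomal RNA, set the wild-type arrays apart from the control and cKI arrays. The 49 tested were chosen after their values were seen. Their mean signal was 8.3 in the wild-type ileum, 8.24 in the wild-type jejunum, 8.06 in the arrays labelled cKO, 7.02 in the control ileum and 7.16 in the cKI ileum. Between control and wild-type ileum 27 were lower and 5 higher, with a median difference of -1.13, and in cKI against control 0 were called by limma and 5 had an unadjusted p below 0.05.

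H2-Ea, an MHC class II alpha chain whose gene is silent in some mouse strains, was seen in few arrays and was chosen after its values were seen. It was at 7.15, 6.05 and 6.82 in the arrays labelled cKO and at 7.77 in control ileum replicate 3. Its mean was 3.5 ± 0.26 (SD) in the wild-type jejunum, 3.75 ± 0.16 in the wild-type ileum and 3.34 ± 0.14 in the cKI ileum. The arrays labelled cKO correlated least with their own group, at 0.972, 0.9742 and 0.9754 on average, and replicates 1 and 3 correlated best with a wild-type ileum array.

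The 3 genes called in the same direction in cKI and cKO were Mt1 (2.01 and 0.96), Gsdmc2, of the gasdermin family (1.25 and 2.34), and Cyp4f13, a fatty acid hydroxylase (-0.61 and -0.72). Gsdmc2 was lower and Cyp4f13 higher in wild-type jejunum than ileum (-2.02 and 1.01). The cKI call of Gsdmc2 was lost without control ileum replicates 2 (adjusted p = 0.128) or 3 (0.103) and cKI ileum replicates 1 (0.176) or 3 (0.147).

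The knockin may lower ileal genes more than it raises jejunal genes. The gap between the ileum-high and jejunum-high index was 0.119 ± 0.133 (SD) in the cKI ileum and -0.055 ± 0.032 in the control ileum, a difference of 0.174 (exact permutation p = 0.1, the smallest possible). Called toward the jejunum were 24 of 233 ileum-high and 17 of 491 jejunum-high genes (Fisher's exact p = 0.000426, across genes that are not independent). With 3 arrays per group the hypothesis stays open.

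Other splits of the same arrays were counted for each result that compared 3 with 3 arrays. There are 10 such splits, too few for a share under 0.05. The other splits also mix the groups compared, whose difference then enters the residual spread and lowers the gene calls. The counts of genes therefore decide nothing about chance. The real split called 2507 genes between regions and the highest of the others 0, as large in 1 of 10. For cKI against control these were 90 and 4 (1 of 10), for cKO against wild-type jejunum 1510 and 0 (1 of 10), and for control against wild-type ileum 3290 and 2 (1 of 10). For cKI ileum against wild-type jejunum they were 4924 and 0 (1 of 10), and for cKO jejunum against wild-type ileum 601 and 0 (1 of 10). Regional genes moved were 5.66% and at most 0.138% in the cKI (1 of 10), and 68.4% and 0% in the cKO (1 of 10). Lists called were 19 and 17 between regions (1 of 10), 15 and 17 in the cKI (3 of 10), 17 and 12 in the cKO (1 of 10), and 2 and 15 in control against wild-type ileum (10 of 10).

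Where replicate numbers paired the arrays by the preset limit, 4 of the 10 splits part all 3 pairs. Of those other than the real split, the highest called 0 genes both between regions and in the cKI, and 14 and 11 lists. The other 6 splits part 1 pair and called at most 0 and 4 genes, and 17 lists in both. For genes opposite in cKI and cKO, 1 of 100 joint splits of both sets of arrays gave as many as the real one, 52, and the highest other gave 1. The calls of the other joint splits let at most 4 genes overlap, so this count decides nothing about chance.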
